A study of Glycine max with 12 samples.

How the data were processed

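Gene expression was measured in trifoliate leaves of 2 soybean lines, Wanxianbaidongdou (WX) and Nannong99-10 (NN), with an oligonucleotide array. Each line had 3 arrays of plants fed on by cotton worm larvae and 3 arrays of untreated plants, 12 arrays in all. Per the labels' protocols, 3 larvae fed on trifoliate leaves over 48 h, with a defoliation of about 20 to 30%. Biotin-labelled cRNA was made from 6 µg of total RNA. The replicates are called biological in the labels, which do not say whether each came from a separate plant. The labels do not name the line that resists the insect, and neither line is called resistant here.

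The deposited values are linear signal intensities, 1 per probe set and array, made with MAS5 per the submitters' processing notes, which give no version; the scaling target is not given in the sources used here. They ran from 1 to 19687.4. The 2% trimmed mean of an array lay between 238 and 263, and its median between 33.0 and 42.1. Of the 61170 probe sets, 37593 were for soybean, 15820 for the oomycete Phytophthora sojae and 7530 for the nematode Heterodera glycines, by their identifiers. The other 227 were controls and ribosomal RNA probe sets, 92 of which held whole numbers only.

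The background of an array was the 95th percentile of its pathogen probe sets. It lay between 45.2 and 60.5 on the WX arrays and between 34.1 and 39.5 on the NN arrays. Soybean probe sets above the background on at least 3 of the 12 arrays were kept, which left 29675 and removed 7918. Fold changes are on the scale of log2(signal + 16), which understates the change of dim probe sets. Where a group was below background on all 3 arrays, the change is given as "at least" a fold against the background of each array or the probe set's own signal, whichever was higher.

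The model was fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays with 1 coefficient per group, so that the 4 groups shared 1 estimate of the spread with 8 residual degrees of freedom. eBayes was run with a trend, tests were two-sided, and probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Feeding was tested in each line, then the difference of the feeding effects (the interaction), then WX against NN in untreated and in fed plants. On data simulated for WX feeding over 29675 probe sets with independent errors, 63 of 100 probe sets changed 2-fold and 91 of 100 changed 4-fold were recovered, and 10 unchanged ones were called. An exact rank comparison of 3 arrays against 3 cannot give a two-sided p under 0.1, and the number of arrays limits the precision of every value.

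Gene symbols came from the array's platform annotation, updated by gene number through a table of the assembly Glycine_max_v4.0, from which no coordinates were taken because the array's build is not given in the sources used here. Of the soybean probe sets, 8677 had 1 symbol, 370 had several genes and 28546 had no symbol here, which does not mean that they have no gene. Of the 1-symbol probe sets 8652 matched the table, and 0 symbols changed. A gene was represented by its kept probe set with the highest mean over all arrays, which gave 5468 genes, 844 of them with a symbol other than a locus number.

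The main model, the alternatives, 39 gene lists and the rule for naming genes were fixed before the data were examined. The lists had been written as patterns on gene descriptions. The tables used here give symbols and no descriptions, so list members were chosen by symbol, before any value was tested. A symbol can mislead: H4, alone in the list of histones and the cell cycle, may not be a histone, and that list is not reported. Lists of seed maturation proteins, aquaporins and bZIP factors were added at that point, and a list of clock genes was added after values had been seen. For the same reason, a gene counted as described if its symbol was not a locus number. The rule names, for each feeding effect, the interaction and the difference between untreated lines, the 10 genes with the largest change each way among those with an adjusted p under 0.05. The values of the groups compared could not overlap, except for the interaction; chance alone gives no overlap in 10% of comparisons of 3 arrays with 3. Up to 3 members of each list with the smallest adjusted p under 0.05 were added, and genes with the smallest changes may be left out. Lists with at least 5 genes were tested with camera at a preset correlation of 0.01, adjusted over 160 tests, and again with an estimated correlation.

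Other pseudocounts, scalings, filters and models of the spread, a block for the replicate number and the removal of each array were tried as alternatives. A covariate for the 18S ribosomal RNA signal was added after seeing the data. Replicates shared numbers across groups. Deviations of same-numbered arrays from their group means correlated between -0.48 and 0.68, with 4 of 12 pairs above 0.1, so the numbers were not treated as pairs. For fed and untreated NN arrays the values were -0.16, 0.68 and 0.67 for replicates 1, 2 and 3. For fed and untreated WX arrays they were -0.36, -0.31 and -0.48. Pairing within NN alone was not tested, as the block fits the same replicate effects in both lines.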

Results

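Leaf transcripts were measured on 12 arrays, 3 for each combination of soybean line (WX or NN) and treatment (48 h of cotton worm feeding or none). The cotton worm is a leaf-chewing caterpillar. Between 25280 and 28960 soybean probe sets were above background on an array. Arrays of a group correlated at 0.932 or more (Spearman, across the kept probe sets), and arrays of different lines at 0.746 to 0.888. The first principal component held 71.2% of the variance and the second 8.28%. On the second, WX fed replicate 1 stood apart at 71.63, with the other arrays between -31.96 and 24.07. The 3′ to 5′ signal ratio of the actin control, a sign of RNA quality, was 3.09 on the WX fed replicate 1, 1.99 and 1.96 on the other WX fed arrays, 2.18 to 2.70 on untreated WX arrays and 2.69 to 3.18 on the 6 NN arrays. The 18S ribosomal RNA control signal was 4516 ± 348 on WX fed, 5081 ± 963 on WX untreated, 6793 ± 2118 on NN fed and 7076 ± 1198 on NN untreated arrays (SD, n = 3 each).

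Feeding on WX raised genes of 7 lists: pathogenesis-related proteins, phenylpropanoid and flavonoid synthesis, glutathione S-transferases, cytochrome P450, and WRKY and NAC transcription factors (camera, preset correlation; 0 lists passed with an estimated correlation). The largest change among named genes was in SMEP1, a metalloendoproteinase, whose signal was 3150 ± 631 in fed and 23.7 ± 2.92 in untreated plants (SD, n = 3 each), at least 53-fold higher (log2 change 6.3, limma adjusted p = 1.3e-07). PR-10, a pathogenesis-related protein, rose at least 8.05-fold and the NAC transcription factor gene NAC26 at least 7.74-fold. Chitinase CHIA1 rose at least 2.93-fold, the heme oxygenase gene HO3 at least 2.18-fold, and the Bowman-Birk protease inhibitor BBI-1 at least 2.61-fold. DIR22, of the dirigent family, rose by 2.71 ± 0.34 on the log2 scale (SE), OLPb, an osmotin-like protein, by 2.62 ± 0.53, WIN by 2.6 ± 0.43 and the cytochrome P450 gene CYP82A2 by 2.52 ± 0.42.

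**Figure D1:**
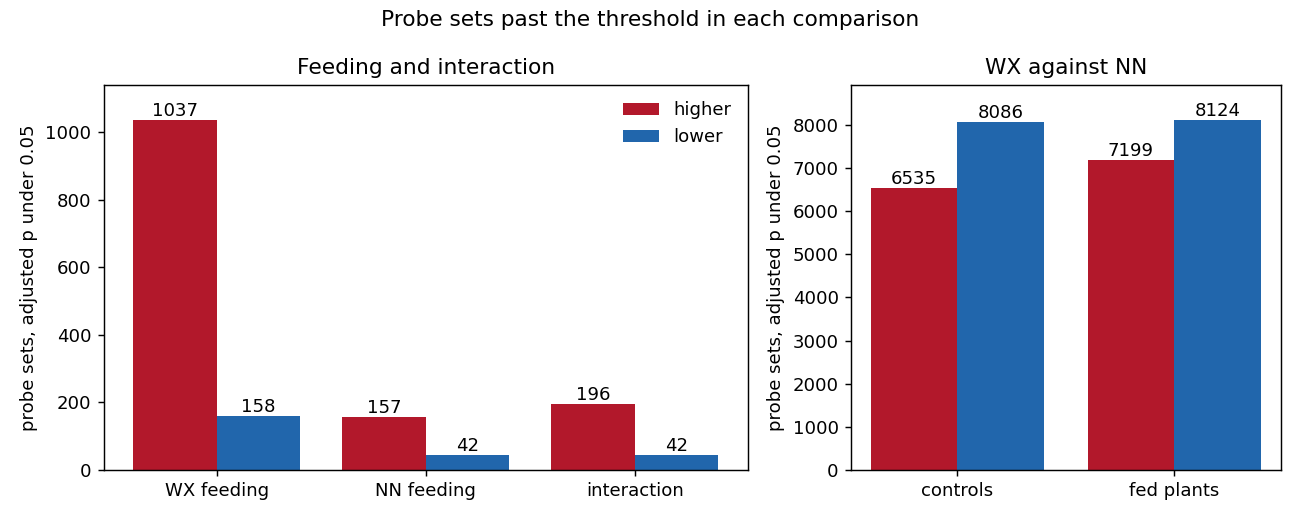
Number of probe sets with an adjusted p under 0.05, higher (red) or lower (blue), in each comparison; the left panel shows the feeding effects and their difference, the right panel WX against NN, on separate linear axes from 0. WX feeding gave 1037 higher and 158 lower, NN feeding 157 and 42.

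In total 1037 of 29675 probe sets were higher and 158 lower in fed WX plants (limma, Benjamini-Hochberg adjusted p under 0.05). Higher calls were 86.8% of the total, against 75.6% after quantile normalization and 74.5% after median centring. WX fed replicate 1, which stood apart on the second component, was kept. Of the lower probe sets 8 were lower by 2-fold or more. Among named genes HSP90A1, a chaperone, fell by 0.85 on the log2 scale, CYP28 fell by 0.77 and the sugar transporter gene SWEET17 fell by 0.71. The count of higher probe sets was 676, 472 and 523 without WX untreated replicates 1 and 3 and WX fed replicate 3, and that of lower ones was 392, 341 and 25 without WX fed replicates 1, 2 and 3, 105, 83 and 37 without WX untreated replicates 1, 2 and 3, 57 without NN fed replicate 1, and 55, 102 and 65 without NN untreated replicates 1, 2 and 3. With only the WX arrays in the fit, 404 were higher and 7 lower. Of the 48 genes named for WX feeding, 16 passed without each array and under every alternative that kept their probe set. They were SMEP1, PR-10, NAC26, DIR22, CHIA1, CYP82A2, HO3, BBI-1, IFR, CHR1, WRKY21, MYB139, GSTU30, HSF-01, PRP2 and SGR1.

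Among the lists, 9 of 41 WRKY transcription factor genes rose and 32 did not pass the test (15 higher and 1 lower when adjusted over the list alone). WRKY21 was raised at least 1.8-fold, WRKY56 by 2 on the log2 scale and WRKY52 by 1.22. The WRKY list as a whole moved up against other genes (camera adjusted p = 4e-05; adjusted p = 0.61 with an estimated correlation). Of 14 NAC genes 5 rose, led by NAC26, NAC34 (1.98) and NAC3 (0.985), and 7 when adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.61 with an estimated correlation). NAC3 had another probe set at -0.20 and GSTU47 2 of 4 probe sets with the opposite sign, the lowest at -0.55, none of them called. Of 54 MYB genes 7 rose, among them MYB139 (1.6) and MYB173 (1.05), and the list did not pass (camera adjusted p = 0.08). Adjusted over the list alone, 14 MYB genes were higher and 1 lower.

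Of 10 phenylpropanoid and lignin genes 3 rose, or 6 when adjusted over the list alone: 4CL1, a coumarate-CoA ligase, by 1.43, CCR by 1.13 and CYP98A2 by 0.90 on the log2 scale (camera adjusted p = 0.0093; adjusted p = 0.68 with an estimated correlation). Of 25 flavonoid genes 4 rose, or 8 with 1 lower when adjusted over the list alone, including the chalcone reductase gene CHR1 by 2.18 and the isoflavone reductase gene IFR at least 2.3-fold (camera adjusted p = 0.036; adjusted p = 0.68 with an estimated correlation). Glutathione S-transferases rose in 3 of 20 cases, such as GSTU30 by 0.81 (camera adjusted p = 0.0093; adjusted p = 0.61 with an estimated correlation). Cytochrome P450 genes rose in 4 of 19, including CYP71D10 by 1.07 (camera adjusted p = 0.025; adjusted p = 0.61 with an estimated correlation). Pathogenesis-related genes rose in 3 of 6, PR-10, CHIA1 and OLPb (camera adjusted p = 0.041; adjusted p = 0.68 with an estimated correlation). The counts adjusted over the list alone were 6, 7 and 3. The call of CYP98A2 was lost in 9 of the 12 runs without 1 array.

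The lipoxygenase gene LOX10 rose by 2.37 ± 0.45 and the allene oxide synthase gene AOS2 by 1.13 ± 0.24 on the log2 scale (SE), each the 1 call of a list of 6 (1 of 6 lipoxygenases and 2 of 6 jasmonate synthesis genes were higher when adjusted over the list alone). Neither list passed (camera adjusted p = 0.23 and adjusted p = 0.55). LOC100778559, a jasmonate repressor known also as JAZ1, rose by 0.77, a call lost in 9 of the 12 runs without 1 array. Its change in NN was 0.86, which did not pass over all probe sets, and the interaction was -0.089. The stay-green genes SGR1 and SGR2, which act in chlorophyll loss, rose by 1.27 and 0.81. The call of SGR2 was lost in 6 of the 12 runs without 1 array. H4, whose product the tables used do not give, rose by 1.65. Its probe set and that of PR-10 share the stem of their identifiers, so the rises of H4 and PR-10 may not be independent. None of 7 photosynthesis genes and none of 8 reference genes passed the limma test, and 0 of either list had an unadjusted p under 0.05.

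Feeding on NN raised a smaller set. CYP82A2 rose at least 13.7-fold, from 20.6 ± 7.23 to 578 ± 312 (SD, n = 3 each; limma adjusted p = 0.0018). The cell wall protein gene PRP2 rose by 2.51 ± 0.23 on the log2 scale (SE) and HO3 by 2.19 ± 0.29. The transcription factor gene MYB184 rose at least 2.17-fold, the phytosulfokine gene PSK5 at least 3.37-fold and CA1 at least 2.06-fold. In WX the PSK5 signal was 193 ± 11.8 in fed and 47.5 ± 6.38 in untreated plants (SD, n = 3 each). In NN the BBI-1 signal was 89.6 ± 57.9 in fed and 9.5 ± 1.03 in untreated plants (SD, n = 3 each). That of CHIA1 was 68.8 ± 40.2 and 11.3 ± 0.947, and that of PR-10 was 77.5 ± 38.4 and 21.1 ± 3.17. BBI-1, CHIA1 and PR-10 were not called in NN, and did not pass the interaction test either. The pathogenesis-related gene PR1-7 rose by 1.37, the peroxidase gene Ep by 1.33, the chaperone gene BIP4 by 1.17 and the aquaporin gene PIP2-9 by 1.1. GLB3 was at least 3.38-fold lower, the isoflavone synthase gene IFS1 fell by 1.35 and the acid phosphatase gene PAP14 fell by 0.88. The call of IFS1 was lost in 10 of the 12 runs without 1 array. LOC547659, of the flavonoid list, rose by 1.54.

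In NN 157 probe sets were higher and 42 lower. The higher count was 75 and 90 without NN untreated replicates 1 and 3. The lower count was 8, 10 and 17 without those and NN fed replicate 1, and 104 without WX fed replicate 1. Of the 16 genes named for NN feeding, CYP82A2, PRP2 and GLB3 passed without each array and under every alternative that kept their probe set. Lists that moved up were those of pathogenesis-related proteins (1 of 6 called, 4 when adjusted over the list alone; camera adjusted p = 7.2e-06; adjusted p = 0.61 with an estimated correlation), cell wall (1 of 10, 2 over the list alone; adjusted p = 0.0093, and adjusted p = 0.61 with an estimated correlation) and jasmonate synthesis. In the jasmonate list 0 of 6 genes passed over all probe sets, 5 had an unadjusted p under 0.05, and 4 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.036; adjusted p = 0.61 with an estimated correlation). None of the 41 WRKY genes passed the limma test in NN, where 5 had an unadjusted p under 0.05 and 2 were higher when adjusted over the list alone.

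Both lines shared 46 probe sets that rose, against 5.49 expected for independent calls, and 1 that fell, against 0.224, while 3 probe sets that rose in WX fell in NN. CYP82A2, PRP2 and HO3 were called higher in each. The comparisons shared no array but shared the estimate of the spread of each probe set, so the calls were not independent and the expected numbers are only a guide. The shared calls in the same direction, 47 in all, were 17 with only the groups compared in each fit and 28 without NN untreated replicate 1. Across probe sets, which are not independent replicates, the changes of the lines correlated at 0.235 (Pearson), and at 0.109 without NN fed replicate 3. Of the probe sets raised in WX 62.2% had a positive change in NN, with a median of 0.09 there and 1.06 in WX. Of those raised in NN 77.7% had a positive change in WX, with a median of 0.46 there and 1.33 in NN.

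**Figure D2:**
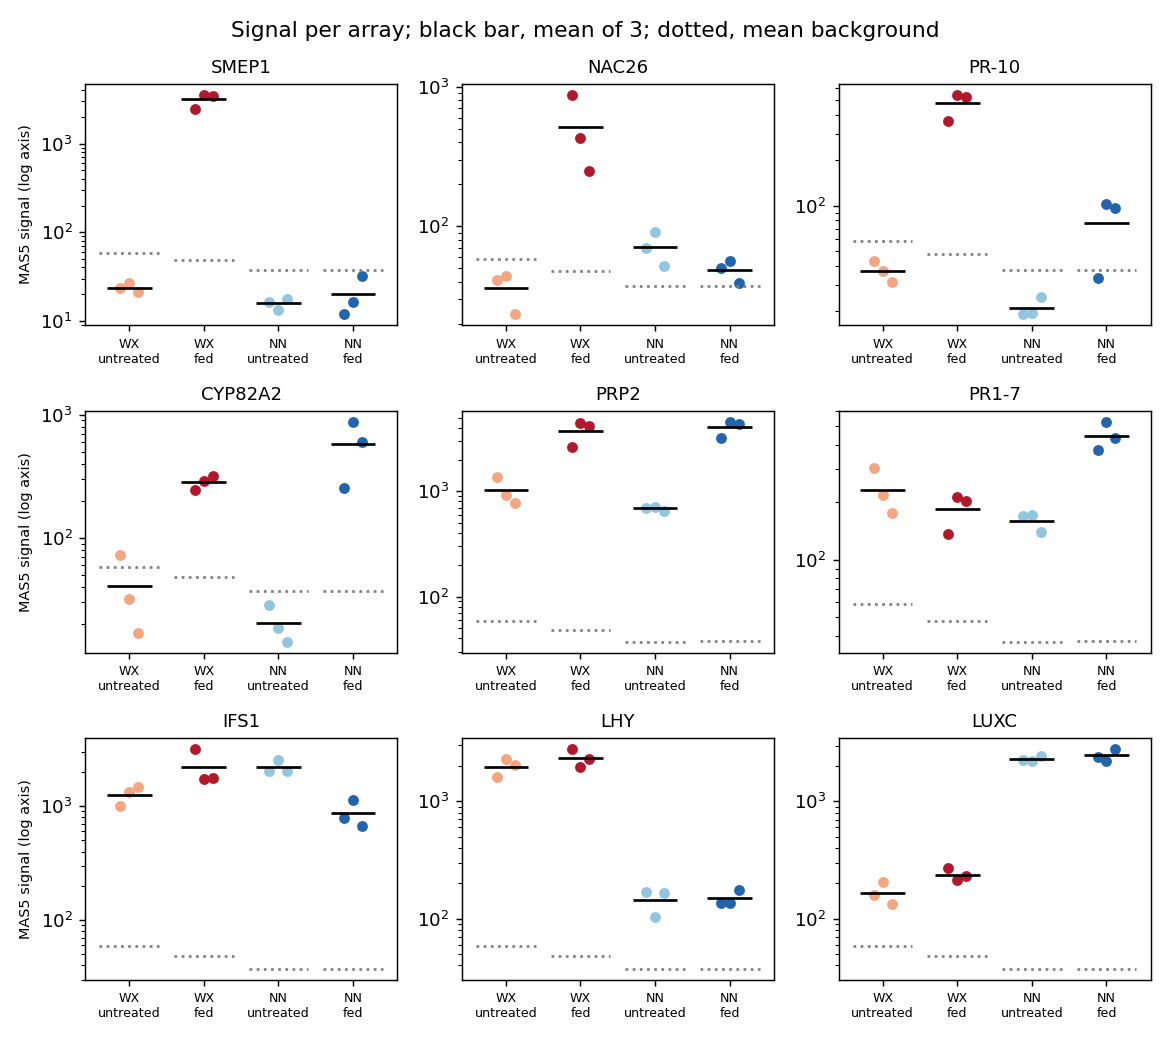
Signal of 9 genes on each array (dots, log axis) by line and treatment, with the mean of 3 arrays (black bar) and the mean background of the group (dotted line). SMEP1 was above background only on the WX fed arrays, and LHY and LUXC differed between the lines with no called change on feeding.

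The interaction tests whether the feeding effects of the lines differ. It is the change in WX less that in NN, and was positive for 196 probe sets and negative for 42. SMEP1, at least 53-fold higher in fed WX plants, was below background in NN with and without larvae, where no change could be seen. Whether its probes bind the NN sequence was not tested. The fitted difference of SMEP1 was 6.16 ± 0.29 (log2 difference of the changes with its SE, limma adjusted p = 7e-06), or 5.72 with signals raised to background. The cysteine synthesis gene OAS-TL6 differed by 2.28. NAC26 and MYB139 had fitted differences of 3.61 and 1.95, each with 1 group below background, and 3.47 and 1.87 with signals raised to background. For WNK5 and WRKY21 the groups other than WX fed were below background, so that the sizes of 2.16 and 1.94 rest on the pseudocount; with signals raised to background they were 0.89 and 0.84. IFS1 had a change of 0.77 in WX, which did not pass the test, and of -1.35 in NN, a difference of 2.12. For PAP14 (0.93) the called change was a fall in NN, with a change of 0.05 in WX that did not pass. GLB3 (1.59) fell in NN and was below background in both WX groups, where no change could be seen. Negative differences were those of PR1-7 (-1.68), PIP2-9 (-1.55), BIP4 (-1.42) and CA1 (-1.25), the last with both WX groups and untreated NN below background. The calls of PR1-7, PIP2-9, BIP4 and CA1 were lost in 8, 7, 8 and 11 of the 12 runs without 1 array. Among positive differences, those of WNK5, IFS1 and PAP14 were lost in 8, 6 and 10 of these runs. CYP82A2 and PRP2 did not pass the interaction test (adjusted p = 0.38 and adjusted p = 0.47).

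For 5 lists the difference was positive. Of 10 phenylpropanoid genes all 10 had a positive difference, with a median of 0.76 on the log2 scale, though 0 passed singly with limma, 5 had an unadjusted p under 0.05 and 5 passed when adjusted over the list alone (camera adjusted p = 0.002; adjusted p = 0.66 with an estimated correlation). The WRKY list (1 of 41 called; adjusted p = 0.0031), glutathione S-transferases (1 of 20; adjusted p = 0.0081), nitrogen and amino acid genes (0 of 9, 4 with an unadjusted p under 0.05; adjusted p = 0.036) and flavonoid genes (2 of 25; adjusted p = 0.042) passed as well, and over the list alone 1, 3, 3 and 2 were called. With an estimated correlation the flavonoid list had an adjusted p = 0.68 and the other 3 lists an adjusted p = 0.61. In NN the median log2 changes of the phenylpropanoid, WRKY, glutathione S-transferase, nitrogen and flavonoid lists were -0.119, 0.061, -0.0215, -0.305 and -0.057. The nitrogen list passed in neither line (camera adjusted p = 0.2 in WX and adjusted p = 0.069 in NN). In NN 1 of its 9 genes had a positive change. Positive calls were 355 and 108 without WX fed replicates 2 and 3, 108 and 109 without WX untreated replicates 1 and 3, 78 and 125 without NN fed replicates 1 and 2, and 70, 117 and 91 without NN untreated replicates 1, 2 and 3. Negative calls were 107, 71 and 14 without WX fed replicates 1, 2 and 3, 14, 21 and 20 without WX untreated replicates 1, 2 and 3, 16 without NN fed replicate 2, and 11, 25 and 12 without NN untreated replicates 1, 2 and 3. SMEP1, NAC26, OAS-TL6, MYB139, WRKY21 and GLB3, of 17 genes named, passed without each array and under every alternative that kept their probe set.

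The untreated lines differed in 6535 probe sets that were higher in WX and 8086 that were lower, 49.3% of those tested. MYB118 was 2170 ± 196 in WX and 37.3 ± 1.26 in NN (SD, n = 3 each; log2 difference 5.35, limma adjusted p = 5e-10), and MYB134, MYB186 and MYB114 were higher by 5.33, by 4.01 and at least 8.76-fold. The ascorbate peroxidase gene APX2 was higher in WX by 6.03, while another of its 3 probe sets was lower by -3.76. BCH5 was higher by 4.07, the ammonium transporter gene AMT1.3 by 3.45 and the heat shock factor gene HSF-03 at least 9.99-fold. Lower in WX were EN2, at least 21.6-fold, PTS1 (-4.09), the seed protein gene P34, at least 4.19-fold, and WRKY43 (-2.69). P34 had another probe set at 0.30, which was not called higher.

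Clock genes stood on both sides. LHY, a morning gene of the circadian clock, was 1970 ± 341 in WX and 145 ± 37.1 in NN (log2 difference 3.63), and its relative LCL3 was at least 9.31-fold higher. LUXC, of an evening gene family, was 166 ± 36.8 in WX and 2290 ± 120 in NN (log2 difference -3.68). The list was made after these values had been seen, the errors are SD with n = 3, and the labels give no time of harvest. None of the 4 clock genes was called on feeding in either line over all probe sets (limma). In WX 1 had an unadjusted p under 0.05, and 1 was higher when adjusted over the list alone. In NN both counts were 0.

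Of 54 MYB genes 20 were higher and 8 lower in WX, over all probe sets and over the list alone (camera adjusted p = 0.036; adjusted p = 0.75 with an estimated correlation). Of 13 sugar and nutrient transport genes 7 were higher and 0 lower, among them SWEET29 by 2.54 and SWEET34 by 2.21, and 8 over the list alone (camera adjusted p = 0.042, and adjusted p = 0.61 with an estimated correlation). Neither the MYB list nor this one passed without a filter. WRKY genes were lower in 18 cases and higher in 5 of 41 (camera adjusted p = 0.069). Flavonoid genes were lower in 10 and higher in 2 of 25 (camera adjusted p = 0.069), such as CHR4, at least 5.49-fold lower. Of 6 lipoxygenases 4 were lower, LOX7 by -2.33, and the list did not pass (camera adjusted p = 0.21). The protease inhibitor genes KTI-2 and KTI-3 were lower by -2.03 and -1.96. In these plants the sucrose transporter gene SUT1 was higher by 3.2, and RCA14, of the Rubisco activases, by 1.01. The background was 58.7 ± 1.83 on untreated WX and 37.4 ± 2.88 on untreated NN arrays (SD, n = 3 each). Of the pathogen probe sets, 4221 of 15820 for P. sojae were higher and 89 lower in untreated WX than NN plants (median log2 difference 0.15), and 1932 and 50 of 7530 for H. glycines (0.13). The actin 3′ to 5′ ratio was 2.43 ± 0.261 on untreated WX and 2.96 ± 0.205 on untreated NN arrays (SD, n = 3 each).

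LHY was 2340 ± 426 in fed WX and 149 ± 21.7 in fed NN plants, LUXC 237 ± 29.3 and 2480 ± 296, and MYB118 2480 ± 170 and 43 ± 10 (SD, n = 3 each). In fed plants 7199 probe sets were higher and 8124 lower in WX. Of these, 5014 higher and 6157 lower ones were called the same way in untreated plants, against 1590 and 2210 expected for independent calls, which these were not, as they shared the spread, and the differences correlated at 0.881 across probe sets (Pearson). MYB genes were higher in 27 and lower in 8 of 54 cases (camera adjusted p = 0.0067; adjusted p = 0.69 with an estimated correlation).

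The pathogen probe sets had a median log2 change on WX feeding of -0.071 for P. sojae and -0.066 for H. glycines, with 113 and 45 probe sets lower and 10 and 2 higher. The background, which is their 95th percentile, was 48.1 ± 4.22 on fed and 58.7 ± 1.83 on untreated WX arrays (SD, n = 3 each). On NN feeding the medians were 0.001 and -0.002.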

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

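The tests of the time of harvest in untreated plants, the check without each clock gene, the ratio of calls without arrays other than WX fed ones or under alternatives other than rescaling, the 18S covariate, and the sizes with signals raised to background were chosen after the result was seen.

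A direct test of the difference between the lines picked out the interaction. It called 196 probe sets higher and 42 lower. Named genes with a positive difference (the change in WX less that in NN, which for GLB3, PAP14 and IFS1 includes a called fall in NN, fitted with the pseudocount) were SMEP1 (6.16), NAC26 (3.61), OAS-TL6 (2.28), WNK5 (2.16), IFS1 (2.12), MYB139 (1.95), WRKY21 (1.94), PPCK1 (1.69), GLB3 (1.59), MYB112 (1.26), GSTU47 (1.07), PAP14 (0.93) and IFR2 (0.68), on the log2 scale; the 4 probe sets of GSTU47 ran from -0.80 to 1.53, with 2 of them positive. Those with a negative difference were PR1-7 (-1.68), PIP2-9 (-1.55), BIP4 (-1.42) and CA1 (-1.25). Their calls were lost in 8, 7, 8 and 11 of the 12 runs without 1 array. Those of WNK5, IFS1, PPCK1 and MYB112 were lost in 8, 6, 4 and 6 of these runs. Those of GSTU47, PAP14 and IFR2 were lost in 11, 10 and 7. All arrays of 3 of the 4 groups were below background for SMEP1, WNK5, WRKY21, GLB3 and CA1, and those of 1 group for NAC26 and MYB139, so these sizes and their order depend on the pseudocount; with signals raised to background they were 5.72, 0.89, 0.84, 1.47, -1.33, 3.47 and 1.87. Lists that differed were phenylpropanoid and lignin (camera adjusted p = 0.002), WRKY factors (adjusted p = 0.0031), glutathione S-transferases (adjusted p = 0.0081), nitrogen and amino acids (adjusted p = 0.036) and flavonoid and isoflavonoid (adjusted p = 0.042), of which none passed with an estimated correlation. Of 100 splits of the fed and untreated labels within the lines, 4 gave as many calls, the real 238 included, a share under 0.05. The highest other split gave 1821, several times the real count. Each line was split on its own, so a split could keep or reverse the real labels of 1 line and carry its feeding effect. The share is thus no clean chance level, and the source of the 1821 calls cannot be told from these counts.

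Pathogen probe sets, outside the main measurement, were higher on WX feeding in 10 cases for P. sojae and 2 for H. glycines, and on NN feeding in 3 cases for P. sojae. Most calls went the other way on WX feeding, with 113 and 45 lower.

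The number of changed probe sets was 1195 on WX feeding and 199 on NN feeding, a ratio of 6.01, and 3 technical explanations were weighed. Without any 1 WX fed array the ratio was at least 2.85 (without replicate 3; 9.03 without replicate 2), and it was 2.64 without WX untreated replicate 3 and 9.17 without NN untreated replicate 1, so no single array of the 12 accounts for all of it, though single arrays change its size. After quantile normalization or median centring it was at least 4.93, which argues against a difference in scale alone. The ratio was 3.35 with the 18S covariate, which gave 1803 calls in WX and 539 in NN. With array weights that did not converge the ratio was 0.197, with more calls in NN, and that value says little. Another split of the NN arrays gave 685 calls against the real 199. Whether a structure of the NN arrays other than feeding lowers the NN count was not tested. Rescaling did not remove a difference in background, which was 45.2 to 52.9 on fed and 56.8 to 60.5 on untreated WX arrays. On WX feeding 2399 of 15820 P. sojae probe sets had an unadjusted p under 0.05 (limma), and on NN feeding 576. Whether this difference between the WX arrays adds to the ratio was not tested. A different time of harvest of fed and untreated WX plants stays open: the median change of 4 clock genes lay at percentile 42.03 of 10000 random lists of like expression, but between 33.3 and 61.7 without each gene, a check added after the first value was seen because 4 genes are few. A different response of the lines, which the design names, stays open as well, and whether the ratio itself exceeds chance was not tested.

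About 49.3% of probe sets differed between the untreated lines. Sequence differences under the probes may account for single cases such as APX2. The agreement given next argues against differences that act on each probe set separately as the whole cause. It cannot exclude differences that affect all probe sets of a gene alike, which would also give agreement. Called probe sets of 1 gene went the same way in 92.7% of cases over 552 genes, against 50% by chance, an excess of 0.427 (95% interval 0.405 to 0.447); some probe sets of a gene share sequence, which raises the agreement. Higher WX background as the whole cause is argued against by the bright probe sets, over 8 times background, of which 49.3% were called. They do not speak for dim probe sets. Of 15820 P. sojae probe sets, 4221 were higher and 89 lower in untreated WX than NN plants. A different time of harvest of the lines cannot be told apart from a genetic difference, because the labels give no time or order of harvest. The clock genes differed more than 100% of random lists (percentile 100), but the list was chosen because LHY and LUXC differed.

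For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest of the others were 1195 and 1 for WX feeding, 14621 and 0 for untreated lines, and 15323 and 0 for fed lines, and 1 split, the real one, reached each. For NN feeding 2 of the 10 splits gave 199 or more, the other 685. That other split set the 3 NN arrays with the highest 18S signal (mean 8147) against the rest (5722). It also put both replicate 2 arrays on 1 side and both replicate 3 arrays on the other. This points to a structure of the arrays. Whether it follows the 18S signal or the replicate number cannot be told from this split, and pairing within NN was not tested.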

How the results depend on the processing

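Named genes kept their direction under every alternative that kept their probe set. Of 193 results 177 were kept by the filter on the mean, and the rest were not counted as lost. In every alternative that kept them, 16 of 48 for WX feeding, 3 of 16 for NN feeding, 6 of 17 for the interaction and 94 of 112 between untreated lines also stayed past the threshold. Counts differed more, and the causes were not tested. The 18S covariate was chosen after seeing the data. The values given are higher, then lower. WX feeding gave 683 and 50 with the replicate block, 404 and 7 with only the groups compared in the fit, 2158 and 1021 with array quality weights, and 564 and 8 at 2-fold or more; lower calls were 256 after quantile normalization, 281 after median centring and 346 with the 18S covariate. NN feeding gave 125 and 23 with the replicate block, 77 and 19 with only the groups compared, 8169 and 7936 with array weights and 370 and 169 with the 18S covariate; 21 were lower at 2-fold. The interaction gave 99 and 16 with the block, 3891 and 2732 with weights, 477 and 137 with the covariate, and 128 higher with the filter on the mean; with only the groups compared its fit is the main one. Array weights did not converge and ran from 0.169 to 69.5, so these counts say little. At 2-fold the untreated lines gave 2468 and 2605 and the fed lines 3135 and 2728. The overlap of 47 feeding calls became 17, 957 and 103 with the groups compared, weights and covariate. Without each array in turn, WX feeding ran from 472 to 1321 and 25 to 392, NN from 75 to 230 and 8 to 104, the interaction from 70 to 355 and 11 to 107, the untreated lines from 5100 to 7288 and 6160 to 8723, the fed lines from 5791 to 7502 and 6246 to 8495, and the overlap from 28 to 69. Each of the 12 arrays left out moved at least 1 feeding or interaction count by over 1.5 times except NN fed replicate 3, without which the correlation of the feeding changes was 0.109, the lowest of a range up to 0.295; with array weights it was 0.1. Same-numbered arrays were not shown to be pairs over both lines (4 of 12 arrays correlated best with their own number). Fed and untreated NN arrays of replicates 2 and 3 did correlate, at 0.68 and 0.67, and a pairing within NN was not tested. Lists past the threshold fell to 0 in every comparison with an estimated correlation; without a filter they were 4 for WX feeding, 3 for the interaction and 0 for untreated lines, which had 1 with the filter on the mean and 4 with the mean over a gene's probe sets, and fed lines had 2 with that mean. Pathogen medians on WX feeding were -0.142 and -0.146 (P. sojae, then H. glycines) with no pseudocount, -0.029 and -0.025 with 64, -0.111 and -0.106 after quantile normalization and -0.126 and -0.121 after centring; called numbers were 42 and 10, 79 for H. glycines with 64, 337 and 166, and 774 and 372. On NN feeding quantile normalization gave -0.056 and -0.059. Probe sets near background limit what can be seen: 7918 were left out.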

Other observations

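Aquaporin genes, a list added with the symbols, were higher in untreated WX than NN plants in 6 of 16 cases and lower in 0, among them NIP2-2 by 2.35, PIP1-8 by 1.69 and PIP2-10 by 1.66 on the log2 scale (camera adjusted p = 0.069). Of 6 seed maturation genes 4 were higher and 1 lower, with PM23 higher by 1.78 (camera adjusted p = 0.16). Of 53 bZIP genes 12 were higher and 16 lower, BZIP58 at least 2.59-fold (camera adjusted p = 0.78). Of 9 calcium signalling genes 6 were lower in WX, such as the calmodulin gene SCAM-5 (at least 1.23-fold), and 1 was higher (camera adjusted p = 0.21). Heat shock genes were higher in 8 and lower in 4 of 15, with HSP23.9 higher by 2.98 and HSP90A1 by 2.54 (camera adjusted p = 0.37).

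Of the unnamed probe sets called, 761 belonged to WX feeding and 125 to NN feeding. The largest rises were 4.31 and 4.21 in WX, and 6.62 and 4.51 in NN, on the log2 scale. The largest decreases were -1.41 and -1.3 in WX and -1.82 and -1.48 in NN.

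The test below was planned before its values were seen, and none in this part was chosen after. Insect RNA on the fed leaves was a hypothesis of its own: it could raise nematode against oomycete probe sets. The medians differed by 0.0048 in WX and -0.0034 in NN, within the bound of ±0.05 set in advance, so no such rise was seen. This sets no limit on insect RNA that these probes do not bind.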
